A study of Homo sapiens with 4 samples.

How the data were processed

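H3K27me3 ChIP-seq was carried out in MCF-7 cells with a GFP vector (control) and in MCF-7 cells overexpressing EPIC1, with 1 immunoprecipitate and 1 input library per condition. Groups and replicate numbers were taken from the sample titles and treatment labels. Per the labels' protocols, cells were fixed with formaldehyde, chromatin was sonicated, and libraries were amplified by PCR and size-selected. The submitters' processing notes name Bowtie2, SAMtools and MACS2 and the build hg38, without versions or settings. Whether the inputs served as the caller's background is not given in the sources used here.

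The deposited files are 2 lists per immunoprecipitate, a list of broad peaks and a list of gapped peaks, called by the authors per library and not on pooled samples. In the deposited files each peak carries a score, a fold enrichment (ratio over the caller's background), and −log10 p and −log10 q values. The gapped list adds a count of narrow blocks with their sizes, as the authors' caller wrote it. Fold and −log10 q are each peak's own deposited values and were used to describe, rank or filter peaks within their list. Numbers and lengths of peaks above a common −log10 q minimum were then compared between the lists, although −log10 q also depends on read depth. The lowest −log10 q was 1.02 in the control list and 1.01 in the EPIC1 list, so 58.0% and 46.6% of the peaks reach a −log10 q of 2. All 58955 control and 51882 EPIC1-library gapped peaks had the position of a broad peak, and 52.3% and 47.3% of the broad peaks held a narrow block of more than 1 bp. Blocks of 1 bp mark only a region's ends and were left out. A read-depth difference between libraries, which the lists do not show, changes how many weak peaks are called and how wide they are.

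Covered length is the sum of broad-peak widths. A peak counted as shared when at least 1 bp met a peak of the other library, and the Jaccard index is the shared length over the joint length. Shares have Wilson 95% intervals. Chance sharing was measured by rotating the EPIC1-library peaks 100 times by random offsets within each of chromosomes 1 to 22 and X. Wide regions are peaks of a library joined at gaps of less than 3 kb and at least 10 kb wide.

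Genes came from the RefSeq table of GRCh38.p14, the same build as hg38, with 19974 protein-coding genes on chromosomes 1 to 22 and X. This table gives gene starts and ends without strand or transcripts, so the planned windows at the transcription start could not be placed. Windows of 1 kb on each side of both gene ends took their place. They take in the 5′ and the 3′ end of each gene and leave out transcripts that start inside it, so the counts are not counts of marked promoters. Cover of a gene's end windows is the covered share of the 2 windows together. Gene-body cover is the covered share from gene start to gene end, and a difference of 0.5 counted. Gene lists held 663 entries, of which 661 matched a symbol; TMEM173, an older symbol of STING1, which is itself listed, and PALI1 did not. The list's mean difference in end-window cover was placed among 10000 random lists of the same size matched on mean cover over both libraries, as a description of these libraries.

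Named genes followed a rule. In each list, up to 4 genes marked in a single library were named per direction, highest fold first. Per direction, 12 protein-coding genes with the highest fold were named among those with at least 50% of an end window covered in one library and no peak of the other within 5 kb. The 3 widest regions per library, overall and without a peak of the other library, were named with their genes, and EPIC1, MYC, CDKN1A, HLA-A, HLA-B, HLA-C, B2M, TAP1, TAP2, ERAP1, NLRC5, IFNGR1, IFNAR1 and STAT1 always. Since strand is not given, the 5 kb rule was first applied to the qualifying end alone, which gave 67 control-only and 54 EPIC1-only genes. After that output was seen it was applied to both ends, which gave 52 and 46. Other genes named as examples within lists were chosen after their values were seen.

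The groups, results, alternatives, gene lists and naming rule were fixed before the data were examined, except that the 5 kb rule was extended to both ends afterwards. Chosen after seeing the data were minimum −log10 q values of 10 and 20, the restriction to chromosomes 1 to 22 and X, the split of covered length by distance to genes, sharing by 4 groups of −log10 q, the 8 gene families, cover by HOX cluster, cover from HLA-F to TAPBP, the 10 Mb bins with their minimum of 20 kb of control cover, the chromosome 8 segments, and the contig rule of 5 kb and a factor of 2. Alternatives were stricter −log10 q minimums, a minimum width of 1 kb, narrow blocks, joined peaks, other overlaps, windows, joining distances and minimum widths, and control peaks kept from the highest fold down until covered lengths matched. This last setting drops control peaks alone, so marks and cover in control can only fall and those in EPIC1 cannot change. It matches length but not number, leaving 31328 control and 51882 EPIC1-library peaks. Analyses used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9. The interval code was tested on simulated intervals: 2420 values were checked with 0 wrong, and 200 of 200 planted losses and 100 of 100 planted gains were recovered. Chromosome Y, unplaced and alternate contigs entered peak totals but no gene count. No p-value or SD between conditions is given because each condition has 1 library.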

Results

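H3K27me3, the histone mark laid down by Polycomb repressive complex 2 and found at silenced genes, was profiled by chromatin immunoprecipitation and sequencing in MCF-7 cells. MCF-7 is an established estrogen receptor-positive line from a breast adenocarcinoma. Cells carrying a GFP vector served as control, and the other culture overexpressed EPIC1, a long non-coding RNA. The 4 samples were 1 immunoprecipitate and 1 input per condition. The 2 immunoprecipitates entered the comparisons below as lists of broad peaks, called separately for each library, and the 2 inputs were not used here. With 1 library per condition there is no replicate, so every difference below describes these 2 libraries and none was tested between conditions. Peak lists do not show how many reads lay behind them, so the sequencing depth is unknown, and each Wilson interval covers counting error over peaks or genes only.

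The first comparison asked how much of the genome lay under H3K27me3 in each library. The largest domains occurred in both. In the control library the widest joined region, 312 kb on chromosome 20 (54395583 to 54707158, hg38), held DOK5, an adaptor protein gene, and EPIC1-library peaks covered 88.8% of it. A 295 kb region on chromosome 12 (132167532 to 132462283) held GALNT9, which encodes a glycosyltransferase of O-linked glycosylation. It was 96.7% covered by control peaks and 95.8% by EPIC1-library peaks. The CELF2 region on chromosome 10 (11002417 to 11285172), named for an RNA-binding protein gene, was 84.8% covered in the control library and 79.2% in the EPIC1 library. The EPIC1 library's second-widest region, 210 kb on chromosome 18 (78656097 to 78866464), held no annotated protein-coding gene.

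The control library held 58955 broad peaks over 124 Mb and the EPIC1 library 51882 peaks over 93.6 Mb, ratios of 0.880 for number and 0.758 for length. Median widths were 1118 bp and 1003 bp. Near gene ends the libraries were closer: the EPIC1-to-control ratio of covered length was 0.920 within 1 kb of protein-coding gene ends, 0.746 in the rest of those genes and 0.743 outside them. The direction depended on significance, and the ratios did not rise steadily. At the planned minimum −log10 q values of 2 and 5 the control library had 34173 and 5690 peaks, the EPIC1 library 24174 and 4540. The number and length ratios were lower there than over all peaks. The minimums of 10 and 20 were chosen after seeing the data. Among peaks whose −log10 q, as the authors' caller gave it, was at least 20, the EPIC1 library had 739 and the control library 574, a number ratio of 1.29 and a length ratio of 1.08. At a minimum of 10 the numbers were 1753 and 1736, a ratio of 1.01. A common minimum need not mean the same enrichment in both libraries, since −log10 q also depends on read depth, which is unknown here.

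**Figure D1:**
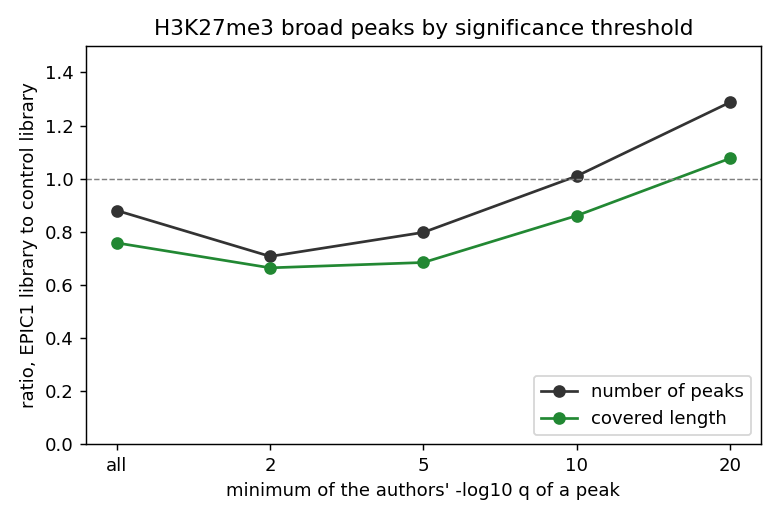
Ratio of the EPIC1 library to the control library (vertical axis, no unit) for the number of broad peaks and for their covered length, among peaks at or above a minimum of the authors' −log10 q (horizontal axis). The number ratio is 0.880 over all peaks and 1.29 at a minimum of 20, the length ratio 0.758 and 1.08. Both are lower at minimums of 2 and 5 than over all peaks. The dashed line marks equal values.

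Wide domains were also fewer in the EPIC1 library, whose covered length was lower. Covered lengths were not matched for wide regions, so this is not a separate difference. After joining peaks less than 3 kb apart, 3587 regions of at least 10 kb remained in the control library and 2581 in the EPIC1 library. Of these, 41 control regions met no peak of the EPIC1 library. The widest such regions were 21.7 kb on chromosome 7 (95487901 to 95509579) at ASB4, an ankyrin-repeat protein gene, 20.3 kb on chromosome 8 (91602857 to 91623128) with no annotated gene, and 17.5 kb on chromosome 7 (28652671 to 28670149) inside CREB5, a transcription factor gene. Only 3 EPIC1-library regions met no control peak, and all 3 lay on chromosome 7 between 61165687 and 61415076 with no annotated gene. Repeat-rich sequence was not filtered out of either list here. With a joining distance of 1 kb no such region remained in either library.

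The second comparison asked whether the peaks lay in the same places. Of the control peaks 54.7% (Wilson 95% interval 54.3 to 55.1) met an EPIC1-library peak by at least 1 bp, and of the EPIC1-library peaks 68.8% (68.4 to 69.2) met a control peak. The libraries shared 67.5 Mb, a Jaccard index over bases of 0.451. When the EPIC1-library peaks were rotated around each chromosome 100 times, the mean shares were 6.11% and 7.28% and the mean Jaccard index 0.0203, against 54.2%, 68.8% and 0.447 observed on the same chromosomes (1 to 22 and X). Sharing rose with significance: it went from 26.96% in the lowest of 4 equal groups of control peaks by −log10 q to 86.1% in the highest, and from 41.8% to 93.8% in the EPIC1 library. Shared peaks were also wider, with medians of 1828 bp against 657 bp for unshared ones in control and 1362 bp against 522 bp in EPIC1. A wide peak meets the rule of 1 bp more easily, and significance and width were not separated here. Of control peaks with −log10 q of at least 5, 95.4% met some EPIC1-library peak, and 98.8% in the other direction. Which library had the larger shared fraction depended on how much had been called: with control peaks kept from the highest fold down until covered lengths matched, 71.5% of control peaks and 50.8% of EPIC1-library peaks were shared. This left 31328 control peaks against all 51882 EPIC1-library peaks, so the EPIC1-library share could only fall. Within the control list the authors' fold enrichment had a median of 3.81 (quartiles 3.36 to 4.49) for shared peaks and 3.26 (3.03 to 3.58) for unshared ones. Within the EPIC1 list the medians were 3.62 (3.21 to 4.31) and 3.10 (2.87 to 3.38).

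The third comparison asked which genes carried the mark at their ends. Because the gene table used gives no strand, a gene counted as marked when a broad peak met the 1 kb on each side of either annotated end, so these counts include marks at the 3′ end. Of 19974 protein-coding genes, 3349 (16.8%, 16.3 to 17.3) were marked in the control library and 3269 (16.4%, 15.9 to 16.9) in the EPIC1 library. Both libraries marked 2747 of them, the control library alone 602 and the EPIC1 library alone 522. With covered lengths matched the split turned, to 210 in the control library alone and 1086 in the EPIC1 library alone. That setting drops control peaks alone and left 31328 of them against 51882 EPIC1-library peaks. Control-only genes can then only become fewer and EPIC1-only genes more, so the turn does not show which library marked more genes.

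Under a stricter rule (at least 50% of an end window covered in one library and no peak of the other within 5 kb of either end), 52 genes were control-only and 46 EPIC1-only. MYCN, a MYC-family oncogene on chromosome 2 (15940550 to 15947004), led the control-only genes: a control peak at 15939046 to 15941983 with an authors' fold of 5.06 and −log10 q of 5.64 covered its lower end, and the nearest EPIC1-library peak was 22.03 kb away. SOSTDC1, a secreted antagonist of BMP and Wnt signalling on chromosome 7 (16461481 to 16465738), had 46.1% of its body covered in the control library and none in the EPIC1 library, with a fold of 3.90. IFNE, an epithelial type I interferon gene on chromosome 9 (21480839 to 21482313), had 27.9% of its body covered in control and none in EPIC1, with a fold of 3.67. The muscarinic receptor gene CHRM3 (fold 4.06), the small GTPase gene RAB7B (4.31), the galanin-like peptide gene GALP (4.03) and the olfactory receptor gene OR6C70 (4.004) were also among the 12 highest. FXYD5 (3.82), LOC107983983 (3.81), LOC112267992 (3.76), the sulfotransferase gene CHST4 (3.69) and the condensin gene SMC2 (3.65) completed them.

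Among the EPIC1-only genes, PGM5, a phosphoglucomutase-like gene on chromosome 9 (68356611 to 68531061), had an EPIC1-library peak at 68356535 to 68357905 with a fold of 6.89 and −log10 q of 8.17. SPRED1, an inhibitor of RAS-MAPK signalling on chromosome 15 (38252836 to 38357249), had a peak at 38251258 to 38253438 with a fold of 5.20, and the nearest control peak was 21.2 kb from the gene. ARNT2, a bHLH-PAS transcription factor gene on chromosome 15 (80404382 to 80597933), had a fold of 4.58 with the nearest control peak 135 kb away. KSR1, a scaffold of the MAPK cascade (fold 4.31), and GRB10, a receptor tyrosine kinase adaptor (fold 4.001), also had peaks at an end. The others were DENND5B (4.48), the PDZ-LIM protein gene PDLIM3 (4.26), the coagulation factor V gene F5 (4.24), LRRC10B (4.16), the glycogenin gene GYG2 (4.10), ZNF454 (4.01) and the microtubule-associated protein gene MAP6 (4.01). Over the whole gene body, cover of PGM5 and F5 was higher in control (1.15% and 0.742%, 6.35% and 4.27%). All 24 genes stayed marked in their own library alone with covered lengths matched, but that setting could not test them. It drops only low-fold control peaks and keeps every EPIC1-library peak, and the control-only genes were picked for high fold. At −log10 q of at least 5 only MYCN and PGM5, 1 per direction, kept a peak.

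The 18 gene lists gave the distribution over gene groups. Here too a mark at either annotated end counted, so a marked gene need not be marked at its promoter. Marks called in 1 library alone depended on the window: of the 22 control and 18 EPIC1 genes named from lists for such a mark, 10 and 11 were marked in both libraries with windows of 5 kb. More genes were marked in control in 5 lists and in EPIC1 in 4, and with covered lengths matched, where only control marks can be lost, in 0 and 9. Genes for neuronal channels and receptors carried the mark most often in both libraries. Of these 57 genes, 46 were marked in each library and 44 in both, among them the glutamate receptor gene GRIN2A (81.8% of its end windows covered in control, 60.1% in EPIC1) and the dopamine receptor gene DRD5 (76.3% and 75.6%). GABRA1 and KCNK9 were marked in control alone, KCNC1 and CACNA1B in EPIC1 alone, though body cover of CACNA1B was 6.63% in control and 6.40% in EPIC1. The control peak covered only 0.2% of the end windows of KCNK9, whose body cover was 4.09% in control and 0.456% in EPIC1. Of 97 developmental transcription factor genes, 50 were marked in control and 54 in EPIC1, with 45 in both. SOX2, SOX14, FOXC1, FOXF1, DLX5 and ASCL1 had 100% of their end windows covered in both libraries. HAND1, a cardiac and trophoblast factor, had 47.4% covered in control and none in EPIC1, and PDX1, a pancreatic factor, 27.3% and none. EN1 and PHOX2A were likewise marked in control alone. OLIG3, FOXD3, OTX1 and PAX1 were among the 9 marked in EPIC1 alone, with 13.9%, 10.0%, 0.875% and 28.9% covered, though body cover of PAX1 was higher in control (8.63% and 6.76%).

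The homeobox clusters, which pattern the body axis, differed from cluster to cluster. Of 39 HOX genes, 15 were marked in control, 19 in EPIC1 and 12 in both. Over the HOXB cluster on chromosome 17 (48528526 to 48728750) covered length was 21.6% in control and 16.0% in EPIC1, and with covered lengths matched 16.1% and 16.0%. HOXB2 went with this, with 86.1% of its body covered in control and 31.9% in EPIC1, as did HOXB4 (100% and 81.0%) and HOXB9 (100% and 74.4%), while HOXB8 was 100% covered in both. The HOXD cluster on chromosome 2 (176087487 to 176190907) had 3.76% in control and 7.45% in EPIC1, and HOXD13 and HOXD10 were marked in EPIC1 alone, with control peaks 1.14 kb and 2.515 kb from these genes. HOXA had 10.2% and 10.98%, with HOXA3 and HOXA10 marked in control alone and HOXA1 and HOXA9 in EPIC1 alone. The HOXC cluster had none in control and 0.652% in EPIC1. HOXC12 was marked in EPIC1 alone, as was HOXC13, by a peak outside the span of the cluster's genes. At −log10 q of at least 5, HOXA turned (4.85% and 2.29%), HOXC and HOXD had no cover in either library, and HOXB had 14.4% and 10.6%. HOXB1 was marked in control alone and HOXB13 in EPIC1 alone. Cover by cluster was computed after single HOX values had been seen.

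**Figure D2:**
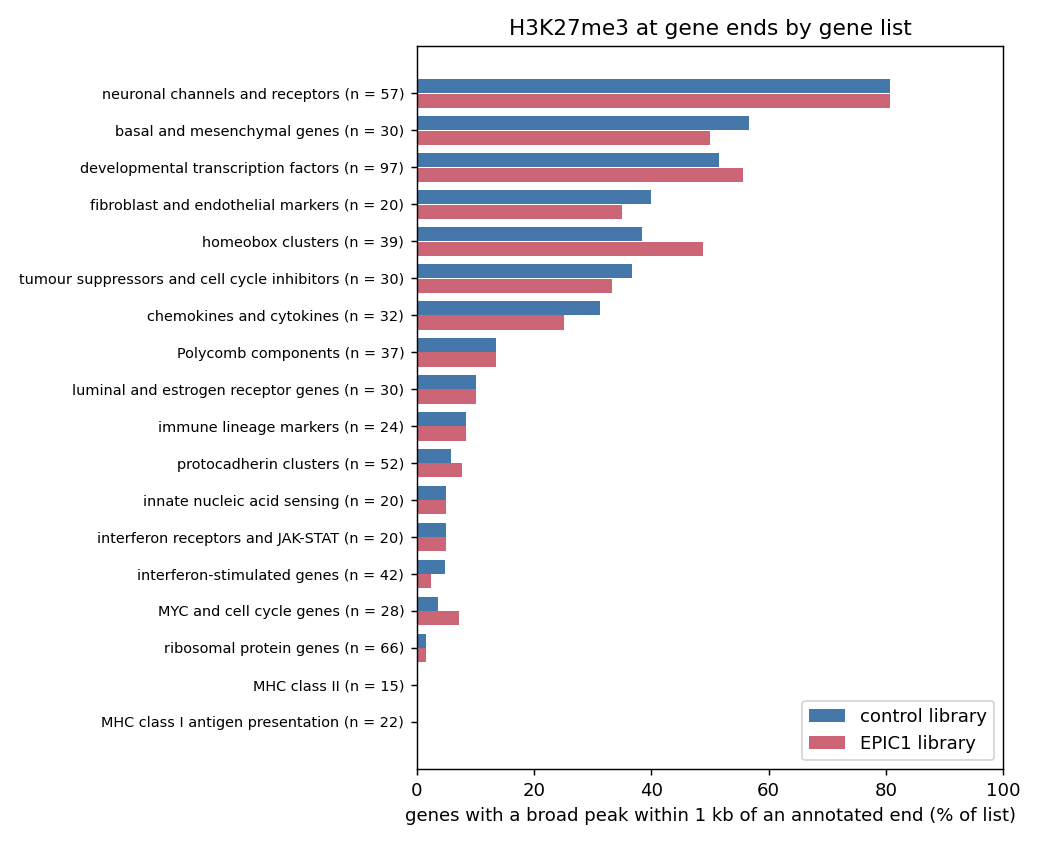
Share of each gene list (horizontal axis, percent of the list's genes) with a broad peak within 1 kb of an annotated gene end, in the control library and the EPIC1 library, 1 library each. Neuronal genes have the longest bars with 46 of 57 genes in each library, and both MHC lists have none.

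Genes of antigen presentation and interferon signalling rarely had a peak within 1 kb of an end in either library. None of 22 MHC class I presentation genes and none of 15 MHC class II genes was marked at an end in either library. HLA-A, which presents peptides on the cell surface, lay 518 kb from the nearest control peak and 223 kb from the nearest EPIC1-library peak. HLA-B lay 97.3 kb and 97.1 kb away, HLA-C 182 kb and 182 kb, B2M 136 kb and 21.7 kb, TAP1 150 kb and 249 kb, TAP2 127 kb and 225 kb, and ERAP1 321 kb and 312 kb. NLRC5, the transactivator of MHC class I genes, had 4.43% of its body covered in control and 3.98% in EPIC1 and no peak at an end. From HLA-F to TAPBP on chromosome 6 (29723434 to 33314078) peaks covered 1.47 kb per Mb in control and 2.59 in EPIC1, against 39.2 and 29.4 over chromosomes 1 to 22 and X. Alternate contigs of chromosome 6 also held peaks, 65.8 kb in control and 90.5 kb in EPIC1, against 5.27 kb and 9.30 kb from HLA-F to TAPBP. They were not assigned to genes here, so the counts and distances for MHC genes hold for the primary chromosome 6 sequence only.

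Of 20 interferon receptor and JAK-STAT genes only IRF8, a myeloid transcription factor, was marked, in both libraries, with 30.4% and 31.6% of its end windows covered. IFNGR1 lay 132 kb and 48.1 kb from a peak, IFNAR1 194 kb and 133 kb, and STAT1 158 kb and 155 kb. Of 42 interferon-stimulated genes, HERC5 was marked in both and USP18, which removes the ubiquitin-like ISG15, in control alone (27.2% covered). Of 20 innate sensing genes only TLR2 was marked at an end, in both libraries. With windows of 2.5 kb 5 were marked in control and 4 in EPIC1, and 4 and 3 had a peak within the gene, among them IFI16 (54.4% and 47.6% of its body) and AIM2 (36.9% and 22.1%). Of 32 chemokine and cytokine genes 10 were marked in control, 8 in EPIC1 and 7 in both, the last including IL6 (50% of its end windows in each) and CXCL12 (50% in each). IL1B (33.9%), CXCL13 (38.3%) and CCL2 (12.8%) were marked in control alone and CXCL16 (26.2%) in EPIC1 alone. An EPIC1-library peak lay 1.67 kb from IL1B, and body cover of CXCL13 was 18.8% in control and 10.1% in EPIC1. With covered lengths matched, 4 chemokine and cytokine genes were marked in control.

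Basal and mesenchymal genes, typical of other breast cell states, were marked in 17 of 30 cases in control, 15 in EPIC1 and 14 in both, and with covered lengths matched in 13 and 15. VIM, the mesenchymal intermediate filament, had 50% of its end windows covered in control and 28.5% in EPIC1, CDH2 (N-cadherin) 50% in each and TWIST1 68.0% and 90.6%. Over this list 8 genes had more end-window cover in control and 7 in EPIC1. SPARC, KRT5 and CD44 were marked in control alone. ZEB1 was marked in EPIC1 alone, with 3.73% of its 1 kb end windows covered by a peak of fold 15.9, and within 5 kb of its ends cover was higher in control. Of 30 luminal genes only GATA3, PGR and STC2 were marked, in both libraries, GATA3 with 50% of its end windows covered in each. Of 24 immune lineage genes NKG7 was marked in both, CD3E in control alone and CD4 in EPIC1 alone, though body cover of CD4 was higher in control (7.19% and 1.61%). Fibroblast and endothelial genes were marked in 8 of 20 cases in control and 7 in EPIC1, all 7 shared, with PECAM1 in control alone.

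Of 30 tumour suppressor genes 11 were marked in control and 10 in EPIC1, all 10 shared, with SERPINB5 in control alone. GAS1, a growth arrest gene, was marked in both, and SFRP2, a Wnt antagonist, had 55.1% and 65.5% of its end windows covered. Over this list mean end-window cover was 15.1% in control and 12.4% in EPIC1, with 4 genes higher in control and 6 in EPIC1. Polycomb component genes were marked in 5 of 37 cases in each library. CBX4, CBX7, CBX8 and BMI1 were marked in both, RING1 in control alone (10.6%) and RNF2 in EPIC1 alone (9.65%). Among 28 MYC and cell cycle genes CDK6 was marked in both and ODC1, the first enzyme of polyamine synthesis, in EPIC1 alone (25.2%). MYC lay 81.8 kb from the nearest control peak and 64.5 kb from the nearest EPIC1-library peak, and CDKN1A, a cyclin-dependent kinase inhibitor gene, 152 kb and 9.23 kb. The EPIC1 gene itself on chromosome 22 (47631674 to 47855600) met no peak in either library, the nearest being 5.28 kb and 78.2 kb away. Of 66 ribosomal protein genes only RPL38 was marked, in both.

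Of 52 clustered protocadherin genes, which encode neuronal adhesion proteins, 3 were marked in control, 4 in EPIC1 and 1, PCDHB12, in both. PCDHB6, PCDHB7 and PCDHB8 were marked in EPIC1 alone and PCDHGA7 and PCDHGA9 in control alone. PCDHB6 had none of its body covered in control and 51.9% in EPIC1, PCDHB7 30.7% and 66.9%. By mean difference in end-window cover, none of the 18 lists lay outside the middle 95% of 10000 random lists matched on cover, and the 2 MHC lists had no cover to compare. This ended under some alternatives. Protocadherin genes lay at percentile 99.6 with windows of 2.5 kb and at 99.98 over gene bodies, where 10 members had more cover in EPIC1 and 14 more in control, and developmental transcription factors at 99.2 over gene bodies. At −log10 q of at least 5, homeobox genes lay at 0.280 and tumour suppressors at 1.73. No other percentile among the 72 list differences recomputed under alternatives lay outside the middle 95%. With 72 values a few would fall outside by chance alone, so none of these percentiles sets a list apart. Protocadherin and homeobox genes lie in clusters, which random lists of scattered genes do not reproduce, so their percentiles do not set them apart.

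The fourth comparison concerned gene bodies. The control library covered at least 50% of the body of 530 genes and the EPIC1 library of 449, with 378 in both. Where cover differed by at least 0.5 of the body, 45 genes had more in control and 22 had more in EPIC1. With covered lengths matched, which lowers control cover alone, these numbers turned to 25 and 50. The examples that follow were chosen after their values were seen. Olfactory receptor genes made up 21 of the 45, such as OR51A2 and OR4K5 (each 100% in control, none in EPIC1), but only 3 of the 22. The chorionic gonadotropin beta genes CGB3 (96.6% and 27.1%), CGB2 (88.5% and none), CGB5 (52.3% and none) and CGB8 (84.0% and none) on chromosome 19 had less in EPIC1. These genes are near-identical copies, so their single values are uncertain. POU3F4, a neural transcription factor, had 83.6% and 8.49%. Keratin-associated protein genes made up 7 of the 22 and 5 of the 45. Developmental transcription factor genes stood in both directions: SOX3 (29.1% and 100%), FOXE1 (7.59% and 65.9%) and NKX2-4 (16.4% and 82.2%) had more in EPIC1. HOXB2 (86.1% and 31.9%), like POU3F4, had more in control. Many genes in these groups are short, where 1 peak can decide the value.

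The last comparison asked whether the difference was local to some chromosomes. The EPIC1-to-control ratio of covered length was below 1 on each of chromosomes 1 to 22 and X. It was lowest on chromosome 14 (2.18 Mb against 3.86 Mb, 0.566) and chromosome 3 (0.629), and highest on chromosome X (2.27 Mb against 2.38 Mb, 0.955) and chromosome 19 (0.889). With covered lengths matched the order kept its ends, 0.806 on chromosome 14 and 1.42 on X. That setting brings the total ratio to about 1, so ratios lie on both sides of 1 by construction, 14 of the 23 above it. At −log10 q of at least 5 chromosomes 14 and 16 were lowest, each at 0.524, and chromosome 22 was highest at 0.854, with X at 0.820. Along chromosome 8 the ratio was 0.454 from 90 to 130 Mb (0.436 to 0.461 in its 10 Mb bins) and 1.31 from 0 to 10 Mb, segments picked after the bins were seen. These were not the extremes. Single bins were lower on chromosome 7 (0.357 at 140 to 150 Mb) and chromosome 1 (0.407 at 190 to 200 Mb). Others were higher on chromosome 4 (2.26 at 60 to 70 Mb) and X (1.45 at 100 to 110 Mb).

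**Figure D3:**
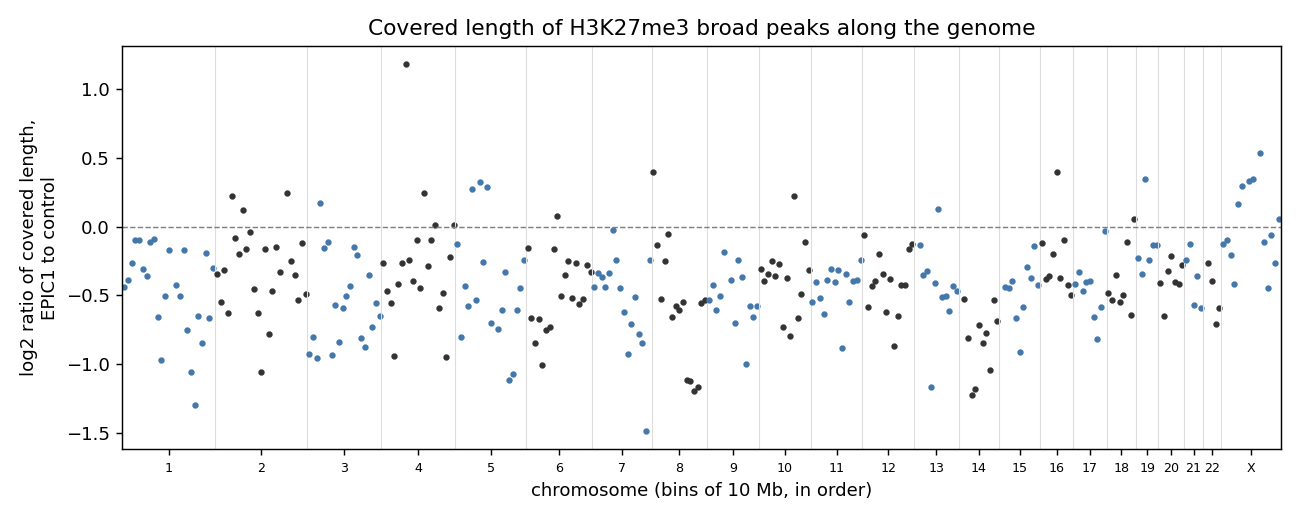
Log2 ratio of covered length, EPIC1 library to control library (vertical axis), in 303 bins of 10 Mb along chromosomes 1 to 22 and X (horizontal axis, colours alternate by chromosome); each point is a bin with at least 20 kb covered in the control library. Most points lie under the dashed line of equal cover, and those from 90 to 130 Mb on chromosome 8 lie together at ratios of 0.436 to 0.461.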

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

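The rule behind these results, contigs outside the numbered chromosomes, X and Y on which EPIC1-library peaks covered at least 5 kb and at least 2 times the control length, was set after the data were seen. Of 188 such contigs with a peak, 5 met it and 12 met its mirror image with the control higher. An alternate contig of chromosome 11 had 6.08 kb covered in the EPIC1 library and 2.65 kb in control. An alternate contig of chromosome 17 had 5.35 kb and 1.94 kb. An unlocalised contig of chromosome 22 had 11.3 kb and 1.58 kb. An alternate contig of chromosome 4 had 5.67 kb and none. An alternate contig of chromosome 6 had 13.004 kb and 3.01 kb.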

How the results depend on the processing

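Minimums of 10 and 20, the restriction to chromosomes 1 to 22 and X, and gene-body cover of named genes were added after seeing the data, and the other alternatives were planned. The start of any annotated transcript was not run, because the gene table used holds no transcripts. No paired analysis was possible because each condition has 1 library. Read depth is unknown here and its effect was not tested. Except where a setting's construction (fewer or narrower regions) shows it, the cause was not tested.

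Of 197 single values recomputed for the comparisons, 122 stayed within their margin (the Wilson interval for shared shares, 2 SE over genes for lists, 1.5 times for the rest), 71 moved, and 4 ratios crossed 1. These counts do not take up which library was higher: matching covered lengths also turned the single-library gene split, the gene-body split, the sign of 6 list differences and the order of the shared shares. Since that setting drops control peaks alone, marks and cover could shift only toward the EPIC1 library. The EPIC1-to-control ratio stayed below 1 for number and length at minimums of 2 and 5, with peaks of at least 1 kb, with narrow blocks, with joined peaks and on chromosomes 1 to 22 and X. It reversed for number at a minimum of 10 (1.01) and for number and length at 20 (1.29 and 1.08). Peak numbers in control and EPIC1 were 34173 and 24174 at a minimum −log10 q of 2, 5690 and 4540 at 5, 1736 and 1753 at 10, 574 and 739 at 20, and 32149 and 26020 with peaks of at least 1 kb. Joining peaks left 37678 in control. Covered lengths were 30.2 and 20.7 Mb at 5, 11.1 and 9.59 Mb at 10, 4.57 and 4.92 Mb at 20, and 44.9 and 31.4 Mb with narrow blocks.

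Shared shares of control and EPIC1-library peaks were 37.1% and 56.7% when 50% of a peak had to be covered, 49.8% and 76.6% at a minimum of 2, 58.5% and 76.1% at 5, 95.4% and 98.8% at 5 against all peaks of the other library, 71.5% and 50.8% with covered lengths matched, 47.8% and 69.4% with narrow blocks, and 56.0% and 75.5% with peaks of at least 1 kb. The Jaccard index stayed within 1.5 times its value in each setting run, as did the 4 median folds.

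Genes marked at an end in control and EPIC1 were 1881 and 1780 with 50% of a window covered (397 and 296 in a single library) and 1458 and 1380 at a minimum of 5 (291 and 213). In a single library they were 210 and 1086 with covered lengths matched, and 394 in control with narrow blocks. Gene bodies with more cover in EPIC1 and in control were 92 and 194 at a difference of 0.25, and 50 and 25 with covered lengths matched. The highest chromosome ratio went from 0.955 to 1.42 with covered lengths matched, where 14 of 23 chromosomes had ratios above 1 against none in the main setting. Since that setting brings the total ratio to about 1, this crossing follows from its construction. The lowest chromosome ratio stayed within 1.5 times.

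Of 72 list differences, 65 stayed within 2 SE over genes and 7 moved. With covered lengths matched 6 changed sign: chemokines from −1.59 to 3.78 points and luminal genes from −0.116 to 0.495, beyond 2 SE, and within it basal and mesenchymal genes (−1.13 to 1.66), developmental transcription factors (−0.532 to 0.929), immune lineage genes (−1.11 to 0.0312) and neuronal genes (−0.229 to 1.47). The sign also changed for 3 lists over gene bodies (developmental transcription factors, homeobox and luminal genes) and for 2 at a minimum of 5 (chemokines, MYC and cell cycle genes). Over gene bodies the values were −0.0205 for MHC class I, −0.326 for MHC class II, −1.54 for innate sensing, 0.208 for luminal genes and 3.41 for protocadherins. Wide regions in control and EPIC1 were 1427 and 868 at a joining distance of 1 kb (0 and 0 without the other library), 5423 and 4533 at 10 kb (367 and 114), 7845 and 6082 at a minimum width of 5 kb (434 and 72), and 1362 and 929 at 20 kb (2 and 0). Of the named genes, ZEB1 reversed to −0.435 points with windows of 5 kb, and over gene bodies PGM5 (−0.405), F5 (−2.09), PAX1 (−1.87), CD4 (−5.57) and CACNA1B (−0.224) reversed. Of the 22 control and 18 EPIC1 genes named from lists, 12 and 7 stayed marked in their own library alone with windows of 5 kb (10 and 11 in both), 17 and 12 with 2.5 kb (5 and 6 in both), 6 and 6 with narrow blocks, 11 and 13 at a minimum of 2, 1 and 2 at 5, and 9 and 18 with covered lengths matched. The 18 could not change in that last setting, since it drops control peaks alone.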

Other observations

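Gene families outside the fixed lists were described after the data were seen, 8 in all. Zinc finger genes were marked at an end more often in the EPIC1 library: of 517 ZNF genes 31 were marked in control and 50 in EPIC1, 26 in both, 5 in control alone and 24 in EPIC1 alone, and with covered lengths matched 19 and 50. Their mean body cover was 0.920% and 0.991%, a difference of 0.0712 points within the range of matched lists (−0.519 to 0.0725). Keratin-associated protein genes had 20.7% and 19.9% of their bodies covered, beta-defensin genes 8.57% and 7.86%, solute carrier genes 3.39% and 2.80%, GPR receptor genes 6.21% and 6.78%, potassium channel genes 11.6% and 8.67%, and interferon alpha genes 9.20% and 6.62%. With covered lengths matched, keratin-associated protein genes had 15.02% and 19.9%, beta-defensin genes 5.46% and 7.86%, and solute carrier genes 2.74% and 2.80%, so that these directions turned. That setting lowers control values alone, so it can move families only in this direction.

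In the control list the highest fold, 26.8, belonged to a 44.2 kb peak on chromosome 19 (36265733 to 36309916) over LINC00665, and a 21.0 kb peak over DUX4L genes on chromosome 10 (133664440 to 133685468) had 24.1. In the EPIC1 list an unlocalised contig of chromosome 22 held the highest fold, 100.2, followed by 2 peaks on chromosome 2 near 91 Mb with 72.2 and 71.0, and by peaks inside ATP10A on chromosome 15 (25757672 to 25760120, 61.1) and PTPRM on chromosome 18 (7566458 to 7568989, 49.2). Each of these peaks met a peak of the other library. Repeat-rich sequence was not filtered out of either list here, so high folds need not mark the strongest domains.

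Of the tests below, those of neighbouring bins and of olfactory receptors among matched single genes were chosen after their result was seen, and that of shifted receptor bodies after a like test on covered bases (ratio 0.769, percentile 58.0 of 552 shifts). Also looked at were the distance of unshared peaks, of which 34.4% (33.8 to 35.0) in control and 39.7% (39.0 to 40.5) in EPIC1 lay within 3 kb of a peak of the other library, and developmental transcription factors, at percentile 89.7 of matched lists by end-window cover.

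The EPIC1 library had less covered length but more peaks of high significance. Repeat-rich contigs alone do not account for the greater number of peaks of high significance. The ratio at −log10 q of at least 20 was 1.30 among peaks at protein-coding gene ends (exact 95% counting interval 1.11 to 1.54, 266 and 347 peaks). This does not address the lower covered length, and gene ends were not screened for repeated sequence. Narrower peaks averaging to a higher significance were examined within width bands. A rule written beforehand counted a lowest ratio of shares with an interval wholly above 1 against this explanation. The rule was met, since that ratio was 1.57 (1.33 to 1.86), over 5 kb. It was set aside and the explanation left open, because the denominators differ (3370 and 4958 peaks). The ratio of numbers there was 1.07 (0.895 to 1.28) against 1.69 (1.29 to 2.24) under 2 kb. A difference in sensitivity or in read depth, which also enters −log10 q, was not tested separately. A library with higher contrast between enriched and other sequence, a different background used in calling, and an effect of EPIC1 also stay open and may each give this pattern, and with 1 library per condition the last was not tested.

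The ratio of covered length differed along chromosomes. Scatter of single peaks is argued against by neighbouring 10 Mb bins, whose log2 ratios correlated at 0.331 over 303 bins, against a highest value of 0.207 in 10000 shuffles. A candidate explanation is copy number that differs between the cultures, which would move peaks near and far from genes together. Their ratios had a Spearman rho of 0.391 over 264 bins (highest of 10000 shuffles 0.261), in a test written after the bins but before this value was seen. Any other regional cause, an effect of EPIC1 included, predicts the same, and the inputs that would show copy number were not used here.

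Olfactory receptor genes had less cover in the EPIC1 library, 15.6% of their bodies in control and 10.1% in EPIC1 over 392 genes, and 11.7% and 10.1% with covered lengths matched. Among lists of single genes matched on cover the family lay at percentile 0, lower than all 10000 drawn. These genes lie in clusters, and when the whole set of bodies was shifted along the genome, its ratio of mean body cover, 0.648, lay at percentile 18.7 of 390 shifts with enough control cover (95% range 0.508 to 0.999). The lower cover may therefore be part of the drop seen elsewhere in the genome, and a change in this family alone is not excluded. Reads shared between receptor paralogs were not tested.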
